A study of Homo sapiens with 6 samples.

How the data were processed

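Small RNA sequencing libraries were made from tumour microvesicles (TMVs) shed by human LOX melanoma cells, an established line, and by a derivative of that line named LOX-Q67L. The labels describe the derivative as ARF6-active, that is, carrying ARF6 in its GTP-bound form. ARF6 is a small GTPase of membrane traffic, and the Q67L form cannot readily hydrolyse GTP. There were 3 libraries per group. Per the labels, both lines were grown in 10% serum and used at passages 3 to 5, and the ARF6-active cells were kept in added selection reagents that the parental cells did not receive. Per the labels' protocols, TMVs were collected by serial centrifugation and small RNAs were purified with a miRvana kit. The library text in the labels describes an Illumina kit for DNA, 15 PCR cycles and gel selection of fragments near 250 bp. The kind of insert, mature miRNA or precursor, is not settled by that text or by counts per mature arm. No molecular identifiers are described, so intervals and floors given here cover counting error only.

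The authors deposited raw read counts per mature miRNA arm for the 6 libraries, in whole numbers and without normalisation. The submitters' processing notes name CASAVA, FastQC, cutadapt and Bowtie2, without versions, order or settings. The genome build, the miRNA reference and the rule for counting reads that match several miRNAs are not given in the sources used here. The table held 2588 mature miRNA names, of which 1967 had a count in at least 1 library. Among the retained miRNAs, 19 names in 9 sets, such as miR-199a-3p and miR-199b-3p, had identical counts in every library, so values of such names stand for their shared reads. Short mature sequences do not separate family members that differ by a single base with certainty, and members of the let-7, miR-30 and miR-548 families are uncertain in that sense.

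Groups were taken from the titles. The total was 429214, 760080 and 525222 counts in LOX replicates 1, 2 and 3, and 2192725, 4707148 and 2315466 in LOX-Q67L replicates 1, 2 and 3. A floor of 3 counts corresponds to between 0.637 and 6.99 CPM (counts scaled to a common library total) in a single library, highest in the shallowest one. Replicate libraries of a group differed by more than sampling noise in every pair, with chi-square values per degree of freedom between 21.3 and 162, and no pair was identical. The labels do not say that replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

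The comparison was made with edgeR 4.0.16 in R 4.3.3. Trimmed mean of M-values (TMM) factors scaled the libraries, filterByExpr retained 442 miRNAs, and the quasi-likelihood test was run without a block, with Benjamini-Hochberg adjustment and a threshold of 0.05. The retained miRNAs held 99.8% to 99.9% of each library's counts. The TMM factors were 1.08, 1.16 and 1.13 in LOX and 1.00, 0.818 and 0.863 in LOX-Q67L. CPM values given in the text are scaled by these factors, except totals of whole lists and count floors, which are plain CPM. Fold changes are LOX-Q67L over LOX. All values are relative to each library's miRNA counts, and CPM scaled by TMM factors are not plain shares of them. Amounts per vesicle or per cell were not analysed here.

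The 20 miRNA lists (families, genomic clusters, melanocyte and melanoma miRNAs, p53-regulated miRNAs, miRNAs often found in vesicles, miRNAs made without exportin-5 or from mirtrons, and markers of other cell types) were fixed before the data were examined, as were the tests, the rule for named miRNAs and the alternatives, apart from thinning and the GC correction. Some members stand in a pair of lists, among them miR-320a, miR-451a, miR-486, miR-30b, miR-30d, miR-145, miR-199a and miR-214. The 18 lists with at least 3 retained rows were tested with camera in limma 3.58.1 on log2 CPM, with a prior count of 2 and a preset correlation of 0.01, and again with an estimated correlation and with fry. For each of 86 precursors with both arms retained, the log2 ratio of the less to the more abundant arm, with a pseudocount of 0.5, was compared with limma. Library-wide measures were taken after every library had been thinned to 429214 counts with a fixed seed, and were compared with exact two-sided permutation tests, whose smallest possible p is 0.1.

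The miRNAs named were the 8 largest increases and the 8 largest decreases among called miRNAs with non-overlapping groups and a mean of at least 10 CPM, the 8 most abundant, and up to 4 members of each list by mean CPM. Any other miRNA named was chosen after its values were seen. Precursor positions, host genes and sequences came from GENCODE release 29 on GRCh38, which need not be the build the authors used; 2585 of the 2588 names matched a precursor gene by name. A position is given only for a mature miRNA with a single precursor gene.

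Alternatives were other scalings (DESeq2 size factors, upper quartile, total counts), DESeq2 1.42.0, limma-voom, other low-count filters, a robust fit, removal of the 3 most abundant miRNAs, a replicate block and removal of each library in turn. Thinning and a per-library loess correction on precursor GC content (span 0.5) were added after the data had been seen. The main test was checked on simulated counts for the same 442 miRNAs with 200 changed: it recovered 75% of 2-fold and 97% of 4-fold changes, and 7 of its calls (3.91%) were false. The arm test recovered 86.7% of 30 precursors with a 4-fold change and made 1 false call. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.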

Results

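The miRNA content of tumour microvesicles was profiled in 6 small RNA libraries, 3 from vesicles of parental LOX melanoma cells and 3 from vesicles of LOX-Q67L cells, which carry active ARF6. The series concerns a route by which ARF6 and exportin-5, the nuclear export receptor of miRNA precursors, bring precursor miRNAs to microvesicles, and the comparison asks how the vesicle miRNA population differs between parental and ARF6-active cells. Libraries held 429214 to 760080 miRNA counts in LOX and 2192725 to 4707148 in LOX-Q67L, so depth differed between the groups. Pearson correlations of log2 CPM were at least 0.965 within LOX, at least 0.990 within LOX-Q67L and between 0.882 and 0.922 across the groups.

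Vesicles of both lines carried largely the same abundant miRNAs, in shifted proportions. miR-21-5p, a miRNA raised in many tumours, was the most abundant and was higher in LOX-Q67L vesicles, at 428412 ± 57373 CPM against 264172 ± 45974 CPM (SD, n = 3 each; log2 fold change 0.70 ± 0.25 SE, edgeR adjusted p = 0.0222). As plain shares of counts, without TMM factors, it held 33.9, 25.9 and 28.7% in LOX replicates 1, 2 and 3. In LOX-Q67L replicates 1, 2 and 3 the shares were 36.3, 38.7 and 38.6%. Its precursor lies on chromosome 17 at 59841266 to 59841337 (GRCh38), in an exon of VMP1. That call was lost when libraries were scaled by total counts alone (0.36, adjusted p = 0.151), without LOX-Q67L replicate 3 (0.68, adjusted p = 0.0778) and after a correction for precursor GC content (0.54, adjusted p = 0.0512), all by edgeR. miR-100-5p, next in abundance, did not differ past the threshold (148929 ± 7797 CPM in LOX and 156843 ± 28829 CPM in LOX-Q67L, edgeR adjusted p = 0.792).

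Among the other abundant miRNAs, miR-30a-5p was 3.63-fold higher in LOX-Q67L vesicles (57657 ± 13945 against 15893 ± 2868 CPM, edgeR adjusted p = 7.48e-06). Its precursor lies on chromosome 6 at 71403551 to 71403621, in an intron of the non-coding gene AL136164.2. miR-151a-3p, from an intron of PTK2, was 2.73-fold higher and miR-7-5p was 2.44-fold higher. miR-3135b moved the other way, from 53947 ± 16256 CPM in LOX to 7796 ± 2876 CPM in LOX-Q67L (log2 fold change -2.79 ± 0.29 SE, edgeR adjusted p = 7.23e-07). Its precursor, on chromosome 6 at 32749912 to 32749979 with no host gene on the same strand, shares a 16-base stretch with an annotated miscellaneous RNA. let-7a-5p was 1.54-fold lower (edgeR adjusted p = 0.0224), a call lost in 4 of the 6 fits that left out a library and without a low-count filter, and let-7i-5p did not pass the threshold (edgeR adjusted p = 0.588).

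The largest increase under the naming rule was that of miR-135b-5p, which stood at 4.08 ± 0.622 CPM in LOX and 66.1 ± 7.50 CPM in LOX-Q67L vesicles (log2 fold change 3.98 ± 0.36 SE, edgeR adjusted p = 1.43e-07). Its precursor lies on chromosome 1 at 205448302 to 205448398, in an intron of LEMD1. The LOX level rested on 2 to 4 counts per library, and the LOX-Q67L level on 115 to 276. miR-137, a regulator of the melanocyte transcription factor MITF, rose 5.99-fold from 4.45 ± 2.24 to 25.5 ± 3.30 CPM. miR-378d, miR-664a-3p and miR-548e-3p rose 5.03-fold, 4.48-fold and 4.01-fold, each from 10 CPM or less in LOX; the precursor of miR-664a-3p shares a 16-base stretch with a small nucleolar RNA. At higher abundance, miR-148b-3p rose 3.67-fold to 5615 ± 1391 CPM and miR-192-5p rose 3.61-fold to 613 ± 72.4 CPM. Both arms of miR-708, chosen after their values were seen, had 0 counts in all 3 LOX libraries. In LOX-Q67L they had 141 counts of miR-708-3p and 93 of miR-708-5p. With 3 counts assumed over the LOX group, miR-708-3p would be 11.3-fold higher and miR-708-5p 7.47-fold higher. The exact 95% counting intervals are wider, with ratios of LOX over LOX-Q67L of up to 0.110 for miR-708-3p and 0.168 for miR-708-5p. The miR-708 precursor lies on chromosome 11 at 79402022 to 79402109, in an intron of TENM4.

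Among miRNAs with counts in both groups, the largest changes were decreases. miR-3168 fell from 2567 ± 2195 CPM in LOX to 89.3 ± 50.6 CPM in LOX-Q67L vesicles (log2 fold change -4.86 ± 0.51 SE, edgeR adjusted p = 7.37e-07). LOX replicate 3 alone held 5094 CPM of it, and without that library the log2 fold change was -3.79. Both arms of miR-483, encoded in an intron of IGF2 on chromosome 11 at 2134134 to 2134209, fell together. miR-483-5p went from 33.8 ± 21.5 to 1.25 ± 1.10 CPM and miR-483-3p from 30.5 ± 15.8 to 1.11 ± 1.14 CPM. The log2 fold change of miR-483-5p was -4.72, and it was -4.05 without LOX replicate 3 and -5.45 without LOX-Q67L replicate 3. miR-155-5p, a miRNA of immune activation, fell from 62.0 ± 52.0 to 3.88 ± 1.01 CPM (log2 fold change -3.90 ± 0.51 SE, edgeR adjusted p = 8.09e-06). LOX replicate 1 held the most, and without it the log2 fold change was -2.89. miR-1207-5p, from an intron of PVT1, fell 18.8-fold, miR-7110-3p fell 13.5-fold, and miR-4508 fell 13.4-fold to 38.9 ± 15.1 CPM. miR-892c-3p had 47 counts over the LOX libraries and 1 over the LOX-Q67L libraries, a ratio of 195 after scaling with an exact 95% counting interval of 33.4 to 7871. Fitted log2 fold changes at such counts depend on single libraries: that of miR-892c-3p was -6.92 and became -7.86 without LOX-Q67L replicate 2, and that of miR-708-3p was 7.84 and became 7.25 without the same library.

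**Figure D1:**
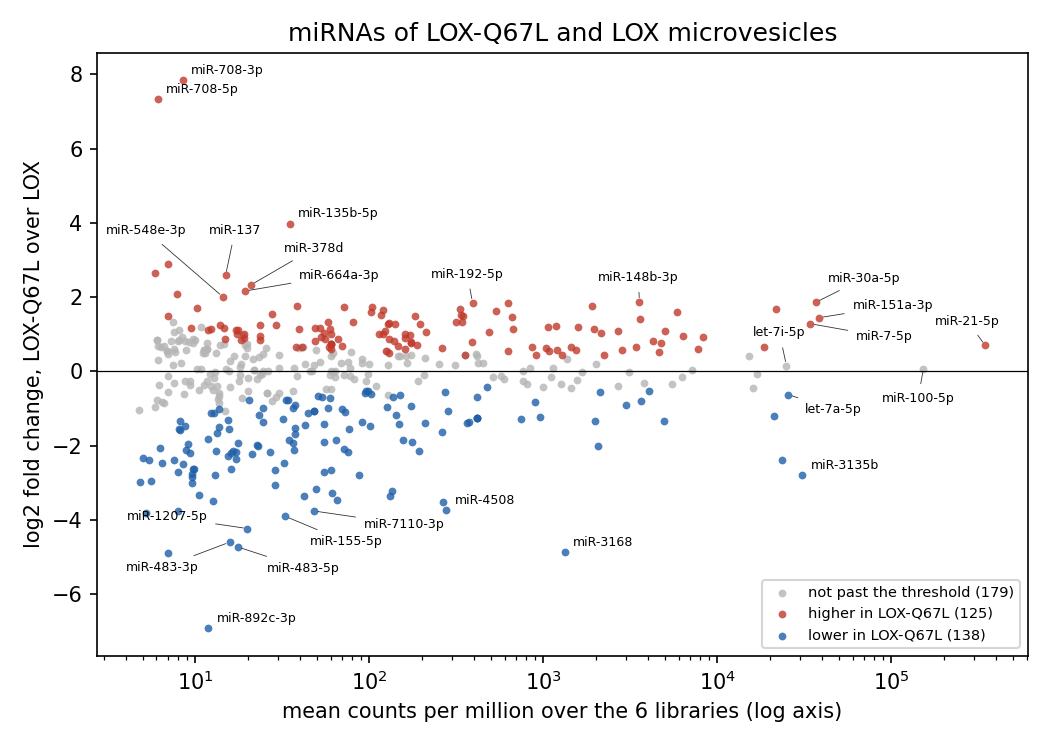
Log2 fold change of LOX-Q67L over LOX vesicles for 442 miRNAs (vertical axis) against mean CPM over the 6 libraries (horizontal log axis); each point is a miRNA, red for the 125 called higher, blue for the 138 called lower and grey for the 179 not past the threshold, and the named extremes and most abundant miRNAs are labelled. Decreases extend to lower values than increases do upwards, apart from the arms of miR-708, whose fitted values rest on 0 counts in LOX and depend on the prior count of the model.

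**Figure D2:**
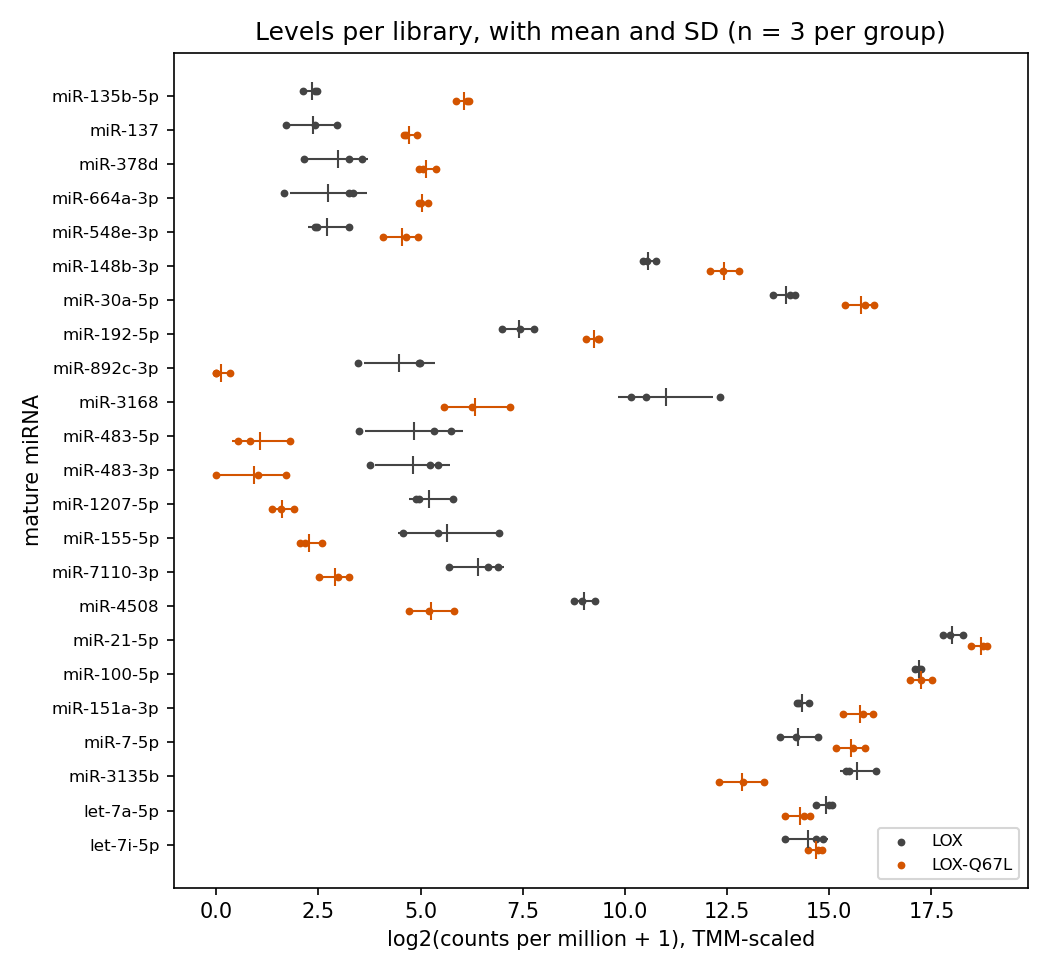
Log2 of CPM + 1 (horizontal axis) of the named extremes and most abundant miRNAs in each library, LOX in grey and LOX-Q67L in orange; dots are single libraries, the vertical tick is the mean and the bar is the SD of 3 libraries. The groups overlap for miR-100-5p and let-7i-5p, the 2 of these miRNAs not past the threshold, and are apart for the others.

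Of the 442 miRNAs tested, 125 were higher and 138 were lower in LOX-Q67L vesicles by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 179 did not pass. A change of at least 2-fold was seen for 73 of the higher and 111 of the lower miRNAs, and a fitted change of at least 8-fold for 3 and 21. The 3 were miR-135b-5p and the arms of miR-708. The counts of miR-708-5p leave a smaller change possible, as it is 7.47-fold higher with 3 counts assumed over the LOX group. The groups did not overlap for 292 miRNAs (66.1%, where chance gives 10%). Directions are relative to the scaling: with total counts alone the median log2 fold change moved from 0.03 to -0.31, and 65 miRNAs were called higher and 167 lower. Without a low-count filter the median of the same miRNAs moved the other way, to 0.39. In that fit 166 of 1967 miRNAs tested were called higher and 122 lower.

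Among the fixed lists, camera called 3 higher and 1 lower. With an estimated correlation no list was called, and 1 of 18 had an unadjusted p under 0.05. Counts adjusted over the list alone equalled those over all miRNAs for every list except the miR-181 family. The melanocyte lineage list, of miRNAs active in pigment cells or acting on MITF, was among those called higher. Of its 9 retained rows, which count both arms of miR-146a and of miR-148b, 7 rose and 0 fell. The camera adjusted p was 0.00895 (0.577 with an estimated correlation), and the call of the list held in each fit that left out a library. No row of miR-211 or miR-204, which the list also names, was retained. miR-146a-5p, a brake on inflammatory signalling, rose 3.20-fold from 10413 ± 1828 to 33363 ± 1942 CPM (edgeR adjusted p = 5.63e-06). Of the clustered miR-182 and miR-183 on chromosome 7, miR-182-5p rose 2.66-fold to 5197 ± 751 CPM and miR-183-5p rose 2.05-fold to 2882 ± 253 CPM. miR-148a-3p and miR-146a-3p did not pass the threshold.

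Of 6 retained miRNAs of the p53-regulated list 5 rose and 0 fell (camera adjusted p = 0.0277; adjusted p = 0.577 with an estimated correlation). miR-34a-5p, a direct p53 target, rose 2.86-fold from 62.2 ± 22.2 to 172 ± 12.1 CPM (edgeR adjusted p = 6.20e-05), and miR-192-5p rose as given above. miR-107 and miR-194-5p rose 1.58-fold and 2.25-fold, and both calls were lost under total-count scaling and after thinning to equal depth. With total counts 3 members of the list rose. The list was not called when any single LOX-Q67L library was left out (camera adjusted p = 0.0695, 0.0543 and 0.0566 without replicates 1, 2 and 3).

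In the miR-30 family, which is expressed in many tissues, 7 of 11 retained rows rose and 0 fell (camera adjusted p = 0.0435; adjusted p = 0.676 with an estimated correlation). miR-30a-3p rose 2.13-fold and miR-30c-5p 1.69-fold, the latter a call lost under total-count scaling (edgeR adjusted p = 0.0940), while miR-30d-5p did not pass the threshold, at 17391 ± 951 CPM in LOX and 16639 ± 1365 CPM in LOX-Q67L. The call of the list was lost without LOX replicate 2 (0.0738) or 3 (0.0538) and without LOX-Q67L replicate 1 (0.0554) or 3 (0.0566), as camera adjusted p.

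The only list called lower was the imprinted DLK1-DIO3 cluster on chromosome 14, in which 7 of 9 retained rows fell and 0 rose (camera adjusted p = 0.0277; adjusted p = 0.577 with an estimated correlation). miR-409-3p fell 4.53-fold from 44.0 ± 31.6 to 9.64 ± 2.45 CPM, with a log2 fold change of -2.18 that became -1.29 without LOX replicate 3. miR-379-5p fell 2.47-fold, a call lost without LOX replicate 3. miR-543 fell 10.0-fold to 1.91 ± 1.34 CPM; its log2 fold change of -3.32 became -2.63 without LOX replicate 1 and -2.68 without LOX-Q67L replicate 2. miR-381-3p, the most abundant member, did not pass (edgeR adjusted p = 0.109). The list was not called without LOX-Q67L replicate 1 (camera adjusted p = 0.0599) or 3 (camera adjusted p = 0.0566).

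**Figure D3:**
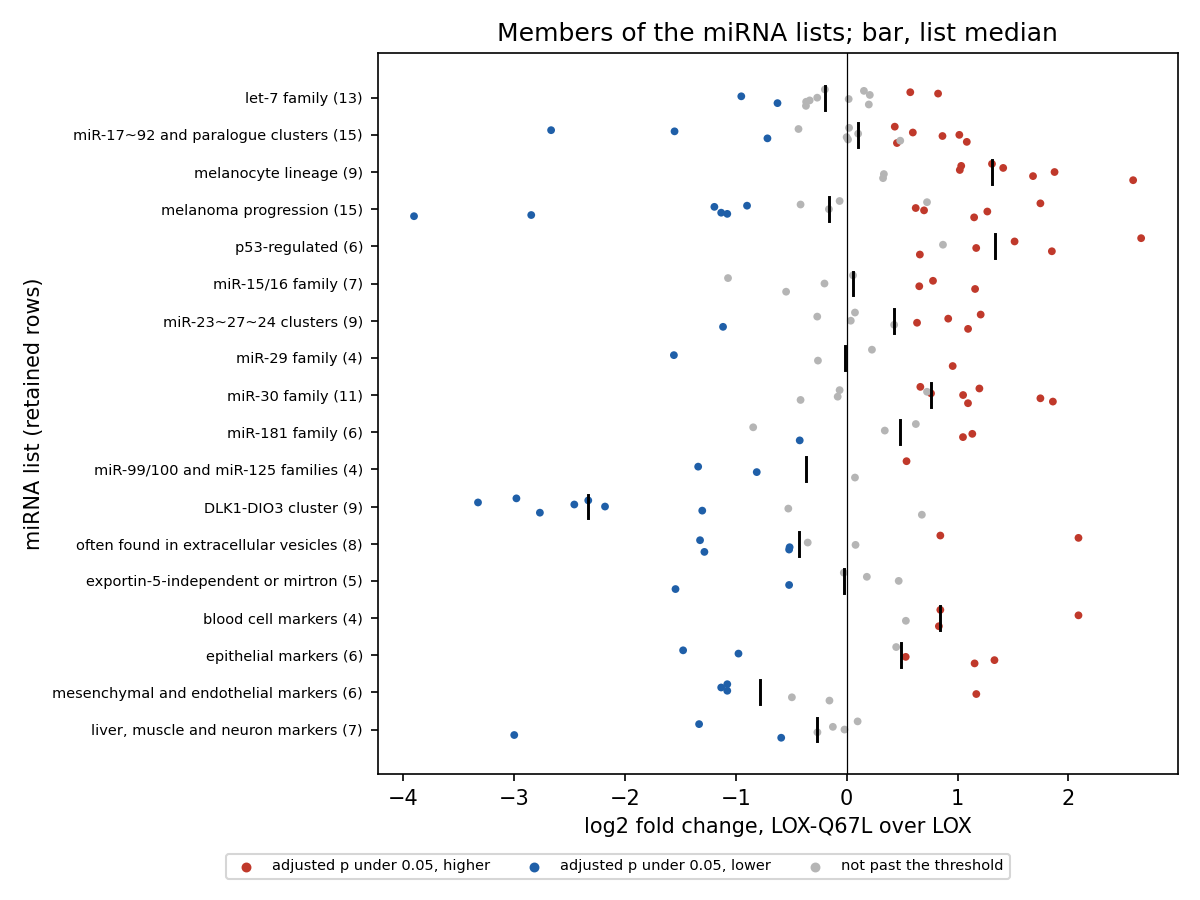
Log2 fold change of LOX-Q67L over LOX vesicles (horizontal axis) of the retained rows of 18 miRNA lists, with the number of rows in brackets; each point is a miRNA, coloured by its call, and the black bar is the list median. The melanocyte lineage list has a median of 1.31 and the DLK1-DIO3 cluster a median of -2.33; under total-count scaling these are 0.97 and -2.69, and the medians of the miR-17~92 and miR-15/16 lists turn negative.

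Other families were not called by camera, and all but the miR-15/16 family had rows called in both directions. In the let-7 family, tumour suppressors in many settings, 2 of 13 rows rose and 2 fell (camera adjusted p = 0.976). let-7f-5p rose 1.77-fold and let-7g-5p 1.49-fold, and both increases were lost under total-count scaling. The call of let-7f-5p was also lost after the GC correction, and that of let-7g-5p without LOX replicate 2 or LOX-Q67L replicate 3. The median and mean log2 fold change of the family were negative (-0.20 and -0.09) while camera gave the direction as higher. In the proliferative miR-17~92 and paralogue clusters 6 of 15 rows rose and 3 fell (camera adjusted p = 0.738), against 1 and 4 under total-count scaling. Of these, miR-25-3p, miR-106b-3p and miR-93-5p from an intron of MCM7 rose 1.51-fold, 1.37-fold and 1.35-fold, none of them past the threshold under total-count scaling or without LOX-Q67L replicate 3. miR-92a-3p, the list's most abundant member, went the other way without passing the threshold. It stood at 18377 ± 2075 CPM in LOX and 13598 ± 1230 CPM in LOX-Q67L (edgeR adjusted p = 0.0681). In 7 of 19 alternatives it was called lower, among them DESeq2, limma-voom and total-count scaling. The list's median was 0.10 and its mean -0.02, and the median was -0.22 under total-count scaling. In the miR-15/16 family 3 of 7 rows rose and 0 fell (camera adjusted p = 0.722), against 1 and 1 under total-count scaling. Its median of 0.06 became -0.31 under that scaling. miR-16-5p was 1.72-fold higher, a call lost under total-count scaling and after the GC correction. In the miR-232724 clusters 4 of 9 rows rose and 1 fell (camera adjusted p = 0.455), with miR-27a-3p 1.89-fold and miR-23a-3p 2.14-fold higher and miR-24-3p at 7037 ± 747 and 7219 ± 902 CPM in LOX and LOX-Q67L. In the miR-29 family 1 of 4 rows rose, miR-29a-3p by 1.94-fold, and 1 fell, miR-29b-1-5p; the call of miR-29a-3p was lost after the correction for precursor GC content (camera adjusted p = 0.976, direction higher against a median of -0.02 and a mean of -0.16, with a median of 0.03 under upper-quartile scaling). In the miR-181 family 2 of 6 rows rose, miR-181a-5p by 2.19-fold and miR-181a-3p by 2.07-fold (camera adjusted p = 0.691). Over all miRNAs tested 1 row fell, against 2 higher and 0 lower adjusted over the list alone. The row that fell, miR-181a-2-3p, lost its call in 11 of 19 alternatives, among them every fit that left out a library. In the miR-99/100 and miR-125 families 2 of 4 rows fell and 1 rose (camera adjusted p = 0.722), with miR-125b-5p 2.53-fold lower at 1121 ± 147 CPM in LOX-Q67L.

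In the melanoma progression list, miRNAs reported to promote melanoma growth or spread, 5 of 15 rows rose and 6 fell (camera adjusted p = 0.871). Under total-count scaling 3 rose and 6 fell. miR-222-3p, a repressor of the cell cycle inhibitor p27, fell 2.29-fold from 29593 ± 5029 to 12944 ± 2117 CPM (edgeR adjusted p = 0.000155), while its cluster partner miR-221-3p did not pass the threshold (edgeR adjusted p = 0.504). Among miRNAs often found in extracellular vesicles 2 of 8 rows rose and 4 fell (camera adjusted p = 0.728). miR-423-5p fell 2.50-fold to 2809 ± 429 CPM and miR-1246, whose precursor shares a 16-base stretch with a small nuclear RNA, fell 2.43-fold to 434 ± 21.3 CPM. Of 5 retained rows of miRNAs that are made without exportin-5 or from mirtrons, 2 fell and 0 rose (camera adjusted p = 0.871). The list pools both kinds, so its values are not a reading of miRNAs made without exportin-5 alone. miR-320a fell 1.43-fold, a call lost without any of 5 of the 6 libraries, and miR-1226-5p fell 2.92-fold, a call lost without LOX replicate 2; both calls were lost after the GC correction. miR-484 and miR-877-5p did not pass (edgeR adjusted p = 0.0610 and 0.935), though miR-484 was called higher under upper-quartile scaling, after the GC correction and without LOX replicate 1, LOX replicate 3 or LOX-Q67L replicate 2. The median of that list, -0.03, was positive under upper-quartile scaling (0.03), without the 3 most abundant miRNAs (0.05), after thinning (0.25) and after the GC correction (0.42).

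Markers of other cell types were read in the same way. Of 4 retained rows of blood cell markers 3 rose and 0 fell (camera adjusted p = 0.216), against 1 and 0 under total-count scaling. miR-142-3p rose 1.78-fold to 178 ± 19.5 CPM, a call lost under total-count scaling. miR-486-5p rose 1.80-fold (edgeR adjusted p = 0.0433), a call lost with DESeq2, with limma-voom, under total-count scaling, after thinning and without any of 4 of the 6 libraries. miR-451a, the erythrocyte miRNA, rose from 2.62 ± 2.87 to 13.1 ± 1.34 CPM on 0 to 5 counts per LOX library; its log2 fold change of 2.09 was 3.77 without LOX replicate 2, and its call was lost after thinning to equal depth (edgeR adjusted p = 0.552). Of 6 rows of epithelial markers 3 rose and 2 fell (camera adjusted p = 0.722), with miR-200a-3p 2.22-fold higher at 927 ± 56.2 CPM. Of 6 rows of mesenchymal and endothelial markers 1 rose, miR-143-3p by 2.25-fold, and 3 fell (camera adjusted p = 0.691). Among the 3, miR-199a-3p and miR-199b-3p had identical counts. Of 7 rows of liver, muscle and neuron markers 0 rose and 3 fell (camera adjusted p = 0.509). Among those that fell, miR-122-5p was 1.51-fold lower at 76.0 ± 8.65 CPM and lost its call without any of 5 of the 6 libraries. miR-128-3p and miR-9-5p of that list did not pass. No miRNA of the X-linked miR-506 cluster or the C19MC cluster was retained by the low-count filter.

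The arms of a miRNA are cut from the same hairpin, or, as for let-7a, from unlike sets of hairpins where it has more than 1 gene, and their balance was compared because the series concerns precursor cargo. The library text describes a DNA kit and library fragments near 250 bp, adapters included, so whether the reads came from mature miRNAs or from precursors is not settled by counts per arm. Of 86 precursors, the share of the less abundant arm rose in 4 and fell in 20 (limma, Benjamini-Hochberg adjusted). For miR-345 the log2 ratio of the less to the more abundant arm went from -1.33 ± 0.78 in LOX to -5.42 ± 0.72 in LOX-Q67L (SD, n = 3; limma adjusted p = 0.00376). For miR-139 it went from -2.30 ± 0.27 to -4.31 ± 0.17 and for miR-25 from -5.74 ± 0.10 to -7.90 ± 0.42. The ratio rose for miR-330, from -4.18 ± 0.35 to -2.42 ± 0.15, and for miR-361, from -3.70 ± 0.10 to -2.87 ± 0.12. These 5 examples were chosen after their values were seen. The lowest count of the less abundant arm in a library was 3 for miR-345 and 8 for miR-139 and miR-330. It was 49 for miR-25 and 53 for miR-361. The median ratio per library was -3.13 ± 0.07 in LOX and -3.26 ± 0.15 in LOX-Q67L, a difference not past the threshold (exact two-sided permutation p = 0.2, smallest possible 0.1). The number of calls depended on depth: after thinning to equal depth 5 precursors were called, 1 up and 4 down. With a pseudocount of 5 it was 39, and it fell to 5, 15, 4 and 8 without LOX replicate 2, LOX replicate 3, LOX-Q67L replicate 2 and LOX-Q67L replicate 3.

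Library-wide measures were compared at equal depth. After thinning to 429214 counts, 899 ± 41.6 miRNAs were detected in LOX and 747 ± 36.5 in LOX-Q67L (SD, n = 3; exact two-sided permutation p = 0.1, the smallest possible), with every LOX library above every LOX-Q67L library. The difference of -152 became -64.7 when detection required at least 5 counts. In the full libraries, which differ in depth, the order was the opposite, and LOX-Q67L had 353 more. The 10 most abundant miRNAs held 73.0 ± 1.29% of counts in LOX and 76.8 ± 3.09% in LOX-Q67L (exact permutation p = 0.2), a difference of 3.82 points that became 2.34 without LOX-Q67L replicate 2. Shannon diversity was 3.06 ± 0.06 in LOX and 2.83 ± 0.13 in LOX-Q67L (exact permutation p = 0.1).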

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

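The thinned and GC-corrected fits were added after the data had been seen. Under every alternative fixed before the data were examined, the total of called miRNAs stayed within 1.5 times that of the main fit, from 208 without LOX-Q67L replicate 3 to 289 without LOX replicate 1, and none of the 263 calls was called in the opposite direction. The number called higher left that range only with total counts, at 65 against 125, where the scaling itself lowered all fold changes. The precursor GC correction called 121 higher and 121 lower; 208 of the 263 calls were kept and 2 were called in the opposite direction. Thinning to equal depth called 94 higher and 124 lower and kept 213. DESeq2 called 107 and 134, and no low-count filter 166 and 122 of 1967 tested. The replicate block called 120 higher and 138 lower, 258 in all, of which 251 were shared with the fit without it. Same-numbered libraries did not deviate together (correlations of -0.07 to 0.04, others -0.14 to 0.15), and 0 of 6 libraries correlated best with its own number. No pairing was seen, but with 3 libraries per group this check cannot exclude a shared day or batch. Under the block the miR-30 list was no longer called (camera adjusted p = 0.0609) and the arm balance calls numbered 8 against 24. Of 1646 values of 88 named miRNAs under the alternatives, 1499 kept the side of the threshold, 108 lost a call and 37 gained it. A change of sign was counted as a reversal only where the main fit or the alternative called the miRNA. Uncalled miRNAs near no change, such as miR-100-5p, could change sign within the 1499. The reversals so counted were those of miR-219a-1-3p. It went from -0.12 (not called) to 0.72 with the GC correction and 0.73 with the GC correction and block, and the cause was not tested. Of 68 named miRNAs called, 42 kept the call under every alternative run. The 4 lists called by camera became 0 with an estimated correlation, 11 with fry, which does not compare a list with other miRNAs, and 1 to 4 when a library was left out (1 without LOX-Q67L replicate 1 or 3). Arm balance calls became 39 with a pseudocount of 5, 5 after thinning and 4 to 28 when a library was left out. Thinning removes counts, and a pseudocount added to raw counts moves the ratios more in the shallower LOX libraries. What this adds to the 39 was not tested, nor was the cause of the other changes. The difference in detected miRNAs, -152 at equal depth, was reversed to 353 in unthinned counts, where LOX-Q67L libraries are deeper. Depth limits the LOX group most: its shallowest library resolves 6.99 plain CPM, without the TMM factor, at a floor of 3 counts.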

Other observations

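The thinned and GC-corrected fits, the arm correlation without extreme precursors, the search for structured RNA fragments and the grouping by miRNA number were chosen after the data had been seen. Some miRNA groups lay below or near the low-count filter, and their totals over all rows are given as values without a test. The DLK1-DIO3 cluster summed to 274 ± 51.6 CPM in LOX and 78.0 ± 13.8 CPM in LOX-Q67L vesicles (SD, n = 3) over 59 rows with a count. The placental C19MC cluster summed to 28.0 ± 10.4 and 5.47 ± 1.41 CPM. The X-linked miR-506 cluster, known from melanoma and testis, had 7 counts in all LOX libraries together and 98 in LOX-Q67L, or 3.60 ± 2.58 and 10.7 ± 1.44 CPM. The melanocyte lineage list summed to 17355 ± 2698 CPM in LOX and 42311 ± 3829 CPM in LOX-Q67L, most of it miR-146a-5p. The miR-30 family summed to 47554 ± 4199 and 81156 ± 5335 CPM.

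The miRNAs lower in LOX-Q67L vesicles were GC-rich and often carry high numbers, which are assigned in the order of discovery. Their precursors had a median GC content of 58.8%, against 50% for those higher and 50.6% for the rest, and 80 of 136 miRNAs numbered 1000 or above fell against 58 of 306 below (Fisher's exact test, odds ratio 6.08, p = 3.48e-16 across miRNAs, which are not independent). These numbers made up 14.4 ± 4.69% of counts in LOX and 3.00 ± 0.89% in LOX-Q67L (exact permutation p = 0.1, the smallest possible), and without miR-3135b and miR-4448 3.41, 4.18 and 4.08% in LOX and 1.86, 1.30 and 1.63% in LOX-Q67L. After the GC correction 121 of all miRNAs tested were still called lower, which argues against a smooth trend with precursor GC content as the whole cause. The median log2 fold change of the 138, -1.83, was -1.26 after that correction, with 111 still called. The 138 were selected in the uncorrected fit, and the GC content of the sequenced inserts is not known. GC bias of another form is therefore not decided. Thinning gave -1.81, with 119 still called at equal depth. Thinning keeps each library's expected proportions, so that median does not decide whether depth, or anything that goes with it, played a part. A 16-base match to an annotated structured RNA was found for 26 of the 138 (18.8%). That share counts names and not reads, and the mismatches allowed in the alignment are not given. The search therefore does not decide whether fragments of such RNAs were the whole cause. The 138 were selected as lower, so the median of -1.56 among those without a match does not bear on that cause. Part of the pattern may still come from GC content or from fragments of structured RNAs. Matches were more frequent among the 138 (26, 18.8%) than among the other 304 (18, 5.92%, Fisher's exact p = 5.89e-05). Nuclear tRNAs and the large rRNAs were not searched. Active ARF6 and the added selection reagents differ between the lines in the same way and remain open. So does anything else that differs between the derived line and its parent, or between the groups of libraries, such as depth.

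The arms of a precursor tended to change together, as a change in precursor supply or loading would give. Across 86 precursors the log2 fold changes of the arms correlated at r = 0.72 (Spearman 0.42), outside the central ranges of -0.22 to 0.22 and -0.21 to 0.21 for randomly re-paired arms (permutation p = 1e-04, the smallest these permutations can give, and 4e-04; precursors are not independent replicates). The size of r rested in part on the extremes, and it was 0.47 (Spearman 0.38) without miR-708 and miR-483, still outside the ranges. Not all pairs need hold separate reads. The arms of miR-4797 had nearly equal counts (log2 ratio -0.009 ± 0.016 in LOX and 0.004 ± 0.005 in LOX-Q67L). The -5p arms of miR-3689a and miR-3689b had identical counts. What such pairs add to r was not tested. The arms had the same sign in 55 (64.0%), against 50.5% on re-pairing. After the GC correction r was 0.71 (0.43 without miR-708 and miR-483). This argues against a smooth trend with precursor GC content as the whole cause. A candidate explanation is a change shared by the hairpin; transcription in the cells, export, loading into vesicles and reads from precursors instead of mature miRNAs are not separated by vesicle libraries, and cellular libraries were not analysed here.

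Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many called miRNAs as the real grouping, which is that grouping itself with 263; the highest of the others gave 0. With 10 splits the share cannot be under 0.05.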
